A study of Mus musculus with 6 samples.

How the data were processed

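Tumours of mice with a heterozygous reporter of Msi2, a heterozygous Ptf1a-Cre, a heterozygous activated Kras allele and floxed Trp53 were dissociated, and EpCAM-positive cells were sorted into GFP-positive and GFP-negative fractions, per the labels' protocols. Stranded mRNA libraries were sequenced from 3 samples of each fraction. The 6 libraries fell into 2 groups by their labels, Msi2-reporter-positive and Msi2-reporter-negative, with replicates numbered 1 to 3 in each. The series' design text calls them biological triplicates. The labels do not say which animals or tumours were used for which library, or whether libraries with one number share a tumour.

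The deposited gene table holds estimated counts per gene for 21045 genes, with gene identifiers and symbols, not normalized. It was taken as estimated counts because 52.5% of the genes with counts had a value more than 0.01 from a whole number in at least 1 library. Per the submitters' processing notes, kallisto, DESeq, DESeq2 and limma and the builds mm10 and GRCm38 were used. The role and version of each tool, the transcript annotation and whether the counting used strand are not given in the sources used here. The authors' second table lists 13787 genes. Its values per library are a score, the estimated counts multiplied by 1 factor per library and rounded to whole numbers by the authors. In that deposited table the smallest mean estimated count of a listed gene was 16. The authors' table also gives group means of that score, a log2 ratio of positive to negative, and false discovery rates, which are p-value-like quantities of the authors' own test, whose name is not given in the sources used here. There were 0 columns of per-sample values that belonged to no sample.

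Estimated counts were rounded to whole numbers. Genes were kept with filterByExpr by group, which left 14190, and these held at least 99.87% of the counts of each library. Libraries were scaled with TMM, and the groups were compared with the edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3) in a model with group alone. P-values were adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. CPM values give the counts of each library relative to its TMM-scaled total. Standard errors of log2 fold changes were taken from the fold change and its F statistic. The p-values of single genes are judged against the spread between the 3 libraries of a group. Those of camera and of the gene families, described below, compare genes with other genes and do not measure that spread alone.

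A set of 31 gene lists (cell types, pathways and gene classes) was fixed before the data were examined. Each list with at least 5 tested members was tested with camera (limma 3.58.1, two-sided, preset correlation of 0.01, on log2 CPM with a prior count of 2), and p-values were adjusted over the 31 lists. Members absent under their symbol were matched through older symbols and gene identifiers in the mouse annotation tables. The genes named in the text follow a rule set at the same time. It takes Msi2, Msi1, Epcam, Kras, Trp53, Ptf1a, Cdkn2a and Rorc. It adds the 10 genes with the largest and the 10 with the smallest log2 fold change among those past the threshold with a mean CPM of at least 5 and groups that do not overlap, leaving out predicted genes and immunoglobulin or T cell receptor segments. It adds up to 4 members of each list with the smallest adjusted p, and the 5 genes with the highest mean CPM in each group. Other genes named (among them Muc13, Pdx1, Ctrb1, Ltf, Jchain, Col1a1, the rising tuft cell genes, Cxcr4, Aldh1a2, Cd44, Plk1, Kif23, Il34, Gli1 and Ptch1, and the members of gene families) were chosen after their values were seen, as examples. Gene positions are from the RefSeq annotation of GRCm38.p6.

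Library totals ran from 15491225 to 25139141 estimated counts, so 3 counts corresponded to between 0.119 and 0.194 CPM. On simulated counts for 14190 genes with the spread of these libraries, the test recovered 3 of 100 genes changed 2-fold and 56 of 100 changed 4-fold. It called 62 genes, of which 3 were unchanged. In a further draw of simulated counts camera called the raised list and 0 of 30 unchanged lists. Genes were simulated as independent, whereas members of the real lists were correlated (estimated at 0.793 for the fibroblast list). This check therefore cannot show how often camera would call unchanged lists in these data. No 2 libraries of a group agreed within sampling noise (smallest chi-square per degree of freedom 56.3). Reads shared between near-identical genes, such as the globin, amylase, cytochrome P450 and mast cell protease genes, can be split between copies by a transcript-level estimate, so the values of single copies are uncertain.

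The alternatives were DESeq2's size factors, no filter, a filter of 5 CPM in 3 libraries, the DESeq2 Wald test (DESeq2 1.42.0), limma-voom, the replicate number as a block, each library left out in turn, and library sizes without the 50 most abundant genes. For the lists they were camera with an estimated correlation, fry, size factors, no filter, the block and each library left out. A run without both libraries numbered 3 was added after the data had been seen. For 1 test libraries were scaled to the epithelial junction and identity list, by the mean over its members of the natural log of CPM + 0.5. This form of the scale was set when the test was run. The reporter transcript itself was not analysed here.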

Results

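Gene expression was measured by RNA sequencing in cells sorted from late-stage mouse pancreatic tumours. The tumours arose in mice in which Ptf1a-Cre, active in the pancreatic lineage, recombines an activated Kras allele and a floxed Trp53. The mice also carried a GFP reporter of Msi2, which encodes the RNA-binding protein Musashi2. EpCAM-positive cells were split by GFP into a reporter-positive fraction, which the submitters label pancreatic cancer stem cells, and a reporter-negative fraction, which they label non-stem. The comparison asks how the transcriptomes of these 2 fractions differ. Each group had 3 libraries. Total estimated counts were 15686531, 21722084 and 25139141 in positive replicates 1 to 3 and 18934107, 23434450 and 15491225 in negative replicates 1 to 3.

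Most tested ductal, gastric mucous and epithelial junction genes and pancreatic transcription factors were higher in the reporter-positive libraries, with list medians of the log2 fold change from 2.77 to 4.06. Most tested myeloid, neutrophil, lymphocyte, endothelial and antigen presentation genes were higher in the reporter-negative libraries, with list medians from -5.97 to -2.41. Of 14190 tested genes, 2774 were higher and 2641 lower in the positive cells (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), together 38.2% of those tested. A log2 change of at least 1 was reached by 2088 of the higher and 1979 of the lower genes, and of at least 3 by 590 and 696. The 2 groups did not overlap for 55.5% of tested genes, against 10% by chance for 3 against 3. Across genes, log2 CPM correlated at r = 0.928 to 0.959 within a group and at 0.711 to 0.83 between groups. Without both libraries numbered 3, a check added after the data were seen, 1794 genes were higher and 1914 lower.

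Msi2 (gene 76626, chromosome 11, positions 88339382 to 88718306 of GRCm38), the reporter's own gene, was higher in each positive library, at 155, 130 and 145 CPM against 38.2, 34.9 and 34.6 CPM. Its mean was 143 ± 12.3 CPM against 35.9 ± 1.96 CPM (SD, n = 3 each), a log2 fold change of 2.0 ± 0.14 (SE; edgeR adjusted p = 0.000612). The sort marker Epcam (gene 17075, chromosome 17, 87635979 to 87651127) was at 1171, 995 and 977 CPM in the positive libraries and at 47.8, 135 and 251 CPM in the negative ones, although both fractions were sorted as EpCAM-positive. Its log2 fold change was 2.86 ± 0.56 (edgeR adjusted p = 0.00773), and 3.51 without negative replicate 3. The paralog Msi1 was low in both groups, at 0.938 ± 0.413 CPM against 1.41 ± 1.29 CPM (SD, n = 3 each), with a log2 fold change of -0.60 (edgeR adjusted p = 0.719) that turned to 0.15 without negative replicate 2 and 0.70 with limma-voom.

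Among the genes of the tumour genotype, Kras (gene 16653, chromosome 6, 145216699 to 145250420) was higher in the positive cells, at 112 ± 10.4 CPM against 55.5 ± 13.6 CPM (SD, n = 3 each; log2 1.01 ± 0.21, edgeR adjusted p = 0.0103). Trp53 (gene 22059, chromosome 11, 69580348 to 69591873), floxed in these mice, was lower, at 14.4, 15.2 and 15.7 CPM against 65.4, 35.7 and 36.9 CPM (log2 -1.61 ± 0.27, edgeR adjusted p = 0.00433). Cdkn2a, which encodes the cell-cycle inhibitors p16 and Arf, was higher at log2 2.40 ± 0.53 (edgeR adjusted p = 0.0117), a call lost without both libraries numbered 3 (adjusted p = 0.0677, the highest over the alternatives, with 1.64e-05 the lowest). Kras and Cdkn2a each rose by less than the median of the epithelial junction list (2.77) in the same libraries. Their values therefore do not show a rise per epithelial cell. Ptf1a, an acinar transcription factor and the Cre driver's locus, was not tested, with estimated counts of 0, 3 and 10 in the positive and 0 in each negative library. Rorc, which encodes a nuclear receptor, was at 50.7, 54.4 and 45.9 CPM against 2.05, 4.57 and 28.6 CPM. Its log2 fold change of 2.11 ± 0.88 did not pass (edgeR adjusted p = 0.0996). Negative replicate 3 decided this, since without it the value was 3.90 (adjusted p = 0.0021, the lowest over the alternatives, with 0.209 the highest). DESeq2 (0.0176) and limma-voom (0.008) also called it.

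**Figure D1:**
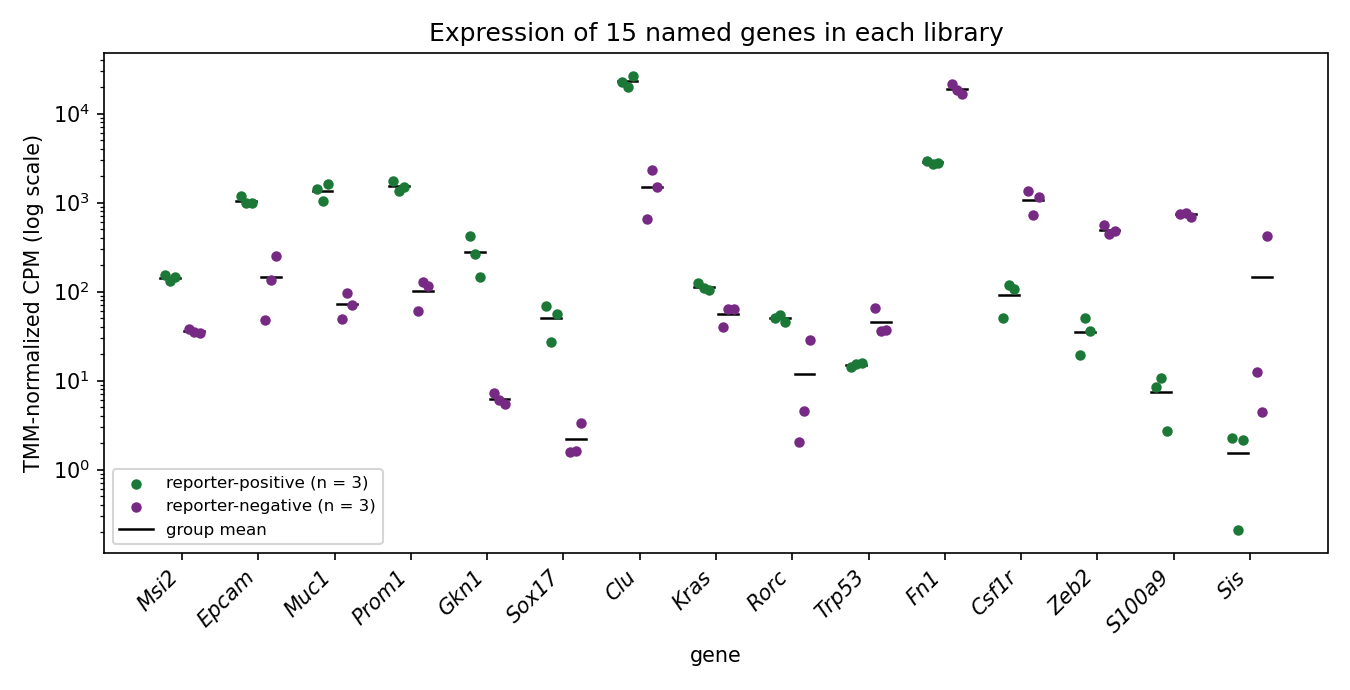
TMM-normalized CPM (log axis) of 15 named genes, with a point for each of the 3 reporter-positive (green) and 3 reporter-negative (purple) libraries and a bar at each group mean. Msi2 sat at 130 to 155 CPM in the positive and 34.6 to 38.2 CPM in the negative libraries, and Sis reached 417 CPM in 1 negative library alone.

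The 10 largest increases by the naming rule had log2 fold changes from 5.20 to 6.07. They were the gastrokines Gkn1 (5.47 ± 0.44) and Gkn2 (5.82 ± 0.82), secreted proteins of the stomach lining, surfactant protein D (Sftpd, 5.33 ± 0.65), the bile acid transporter Slc10a2 (5.57 ± 0.37), the galactosyltransferase Ugt8a (6.07 ± 0.62), Vsig2 (5.20 ± 0.54), Syt16 (5.36 ± 0.49), Spock3 (5.27 ± 0.97), Mfi2 (5.30 ± 1.03) and Bpifb1 (5.36 ± 1.28). Gkn1, for example, was at 276 ± 139 CPM against 6.24 ± 0.893 CPM (SD, n = 3 each; edgeR adjusted p = 0.000642), and Slc10a2 at 10.6 ± 0.601 CPM against 0.219 ± 0.0435 CPM. Bpifb1 was at 18.4, 40.1 and 1.78 CPM in the positive libraries, and its edgeR adjusted p of 0.0163 became 0.0506 without negative replicate 1 (highest over the alternatives 0.202, with limma-voom). The values of Gkn2 without positive replicate 1 (4.87), Mfi2 without positive replicate 3 (4.25), Spock3 without negative replicate 2 (6.41) and Ugt8a without negative replicate 3 (6.78) differed by over 1.5 times in fold. Mfi2 also moved to 6.11 without negative replicate 3, and Bpifb1 to 4.41 without positive and 6.51 without negative replicate 2. Spock3 lost its call without both libraries numbered 3 (adjusted p = 0.0624; range over the alternatives 0.000474 to 0.0624).

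The 10 largest decreases by the naming rule, which leaves out genes whose groups overlap, had log2 fold changes from -7.85 to -6.55. The neutrophil and myeloid genes among them were Stfa2l1 (-7.85 ± 0.81), the metalloproteinase Mmp25 (-7.02 ± 0.72), the resistin-like Retnlg (-6.90 ± 0.60), G0s2 (-6.75 ± 0.31) and the calprotectin subunit S100a9 (-6.65 ± 0.56), with Abca13, a lipid transporter family member, at -6.74 ± 0.53. S100a9 was at 7.36 ± 4.17 CPM against 736 ± 43.2 CPM (SD, n = 3 each; edgeR adjusted p = 0.000684). Without positive replicate 2, Stfa2l1 was at -9.52 and Mmp25 at -8.09, and without positive replicate 3 Stfa2l1 was at -7.21. The other 4 had much smaller fold changes without negative replicate 3. Sis, the intestinal enzyme sucrase-isomaltase, was at 12.6, 4.48 and 417 CPM in the negative libraries, and its log2 fold change of -6.55 was -2.45 without that library (adjusted p = 0.0912). The cytochrome P450 gene Cyp3a11 (2.40, 1.13 and 166 CPM) went from -6.96 to -1.99 (adjusted p = 0.0743). Its relative Cyp3a25 went from -7.29 to -3.74 (and to -8.65 without positive replicate 3), and the granzyme gene Gzma from -6.93 to -3.07. Without negative replicate 3, Cyp3a25 (edgeR adjusted p = 0.0365) and Gzma (0.017) stayed past the threshold. Each of the 4 lost its call without any 1 of the positive libraries, with adjusted p from 0.0683 to 0.112, and with limma-voom, with adjusted p from 0.127 to 0.367.

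The most abundant transcripts of the positive libraries were Clu, the chaperone clusterin (23000 ± 3320 CPM against 1503 ± 842 CPM, SD, n = 3 each; log2 3.94), and Dmbt1, a secreted mucosal glycoprotein (14170 ± 2299 CPM against 1178 ± 1225 CPM; log2 3.59, and 4.90 without negative replicate 3). Those of the negative libraries were Fn1, fibronectin (18750 ± 2415 CPM against 2823 ± 120 CPM; log2 -2.73), the macrophage products Chil3 (log2 -3.68, and -4.33 without positive replicate 2) and Lyz2 (-3.24), and Psap (-2.21). All 6 passed the edgeR test, with adjusted p from 0.000969 to 0.0112. The mitochondrial COX1 and the elongation factors Eef1a1 and Eef2, also among the most abundant, had log2 fold changes of -0.11, 0.29 and 0.40 and did not pass (edgeR adjusted p = 0.808, 0.444 and 0.267).

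Of the 31 gene lists fixed before the data were examined, 19 were past an adjusted p of 0.05 with camera at its preset correlation and 0 with an estimated correlation. The smallest camera adjusted p with an estimated correlation was 0.48, so each list is described mainly by its members. Unless stated otherwise, counts of members are from the edgeR test adjusted over all genes, followed by the count adjusted over the list alone. Of all tested genes 19.55% were higher and 18.61% lower. Counts near or under those shares, as in the DNA replication list, do not set a list apart.

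**Figure D2:**
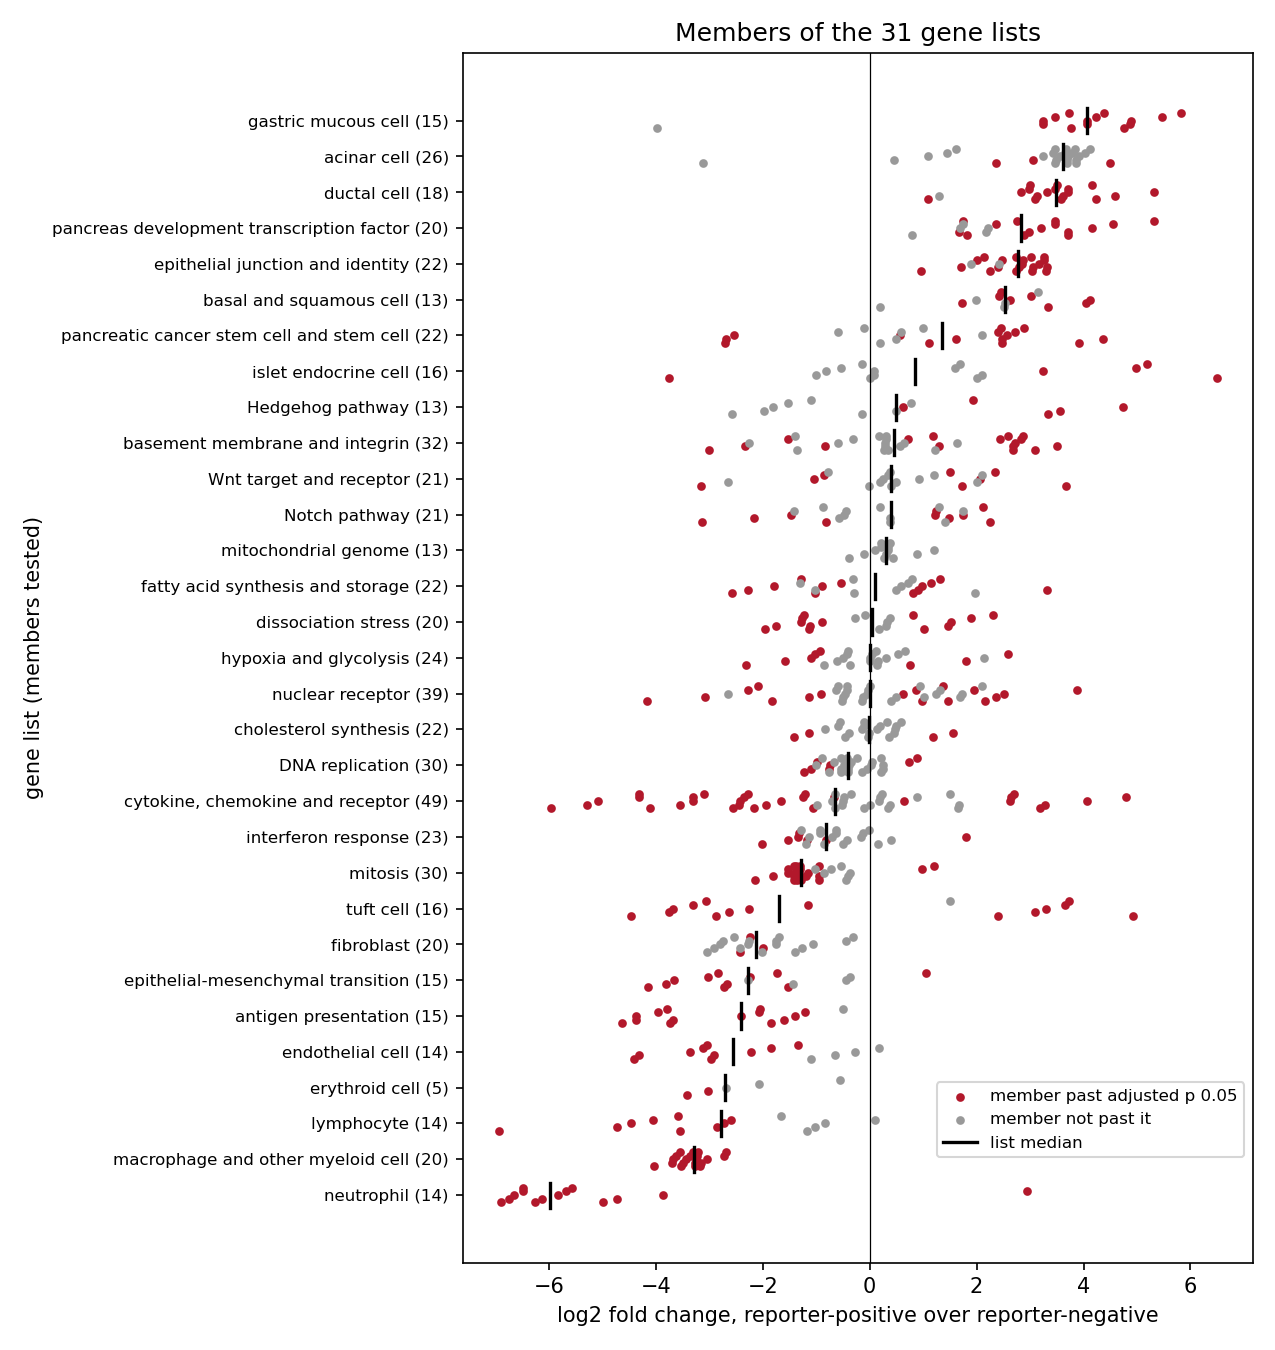
Log2 fold change of reporter-positive over reporter-negative cells (horizontal axis) for each tested member of the 31 lists (rows, with the number tested), coloured by whether it passed adjusted p 0.05, with a bar at each list median. Medians ran from -5.97 for the neutrophil list to 4.06 for the gastric mucous list.

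Ductal genes were higher nearly throughout: 17 of 18 rose and 0 fell (17 and 0 adjusted over the list alone), with a median log2 of 3.49 (camera adjusted p = 4.75e-08, and adjusted p = 0.48 with an estimated correlation). The membrane mucin Muc1 (gene 17829, chromosome 3, 89229056 to 89233381) was at 1353 ± 287 CPM against 71.7 ± 23.3 CPM (SD, n = 3 each; log2 4.24 ± 0.33, edgeR adjusted p = 0.000639). The carbonic anhydrase Car2 (4.58), the duct cilium gene Pkhd1 (4.16) and the duct transcription factor Hnf1b (3.70) rose as well. Gastric mucous genes rose in 14 of 15 and fell in 0 (14 and 0 adjusted over the list alone), with a median of 4.06 (camera adjusted p = 3.72e-07, and adjusted p = 0.48 with an estimated correlation). Besides the gastrokines these included the trefoil peptide Tff2 (4.37 ± 0.32) and cathepsin E (Ctse, 4.06 ± 0.34). The mucin Muc13, at -3.98, did not pass (edgeR adjusted p = 0.11). It was at 426 CPM in negative replicate 3, and its value was 0.78 without that library.

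Epithelial junction and identity genes rose in 20 of 22 and fell in 0 (22 and 0 adjusted over the list alone), with a median of 2.77 (camera adjusted p = 3.54e-08, and adjusted p = 0.48 with an estimated correlation). Examples were the desmosomal plakoglobin Jup (2.14 ± 0.22), the polarity protein Crb3 (3.30 ± 0.36), the membrane protease St14 (3.26 ± 0.39) and the splicing factor Esrp2 (3.17 ± 0.39). Summed over the list, the positive libraries held 6502, 4805 and 5734 CPM and the negative ones 495, 868 and 1410 CPM. Pancreas development transcription factors rose in 15 of 20 and fell in 0 (15 and 0 adjusted over the list alone), with a median of 2.83 (camera adjusted p = 1.17e-06, and adjusted p = 0.48 with an estimated correlation). Sox17 (4.54 ± 0.49), Foxa2 (3.71 ± 0.34) and Glis3 (2.90 ± 0.41) were among them, while Pdx1, at 2.18, did not pass (edgeR adjusted p = 0.1) but was at 3.55 without negative replicate 3 (adjusted p = 0.0157; range over the alternatives 0.0147 to 0.214). Basal and squamous genes rose in 8 of 13 and fell in 0 (10 and 0 adjusted over the list alone), with a median of 2.54 (camera adjusted p = 0.000247, and adjusted p = 0.48 with an estimated correlation). They included the serpin Serpinb5 (4.11, and 4.92 without negative replicate 2), stratifin (Sfn, 2.46, and 3.16 without negative replicate 3) and Perp (1.73 ± 0.27).

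Acinar genes had a median of 3.61 (camera adjusted p = 0.00303, and adjusted p = 0.711 with an estimated correlation), yet 3 of 26 rose, 0 fell and 23 did not pass (2 and 0 adjusted over the list alone). Positive replicate 3 stood apart: its summed acinar CPM was 4833 against 861 and 446 in the other positive libraries and 81.7, 136 and 1348 in the negative ones. The chymotrypsinogen Ctrb1 was at 113, 41.4 and 1334 CPM in the positive libraries and at 6.3, 29.6 and 77.6 CPM in the negative ones. Reg1 alone gave 403, 219 and 654 CPM of the sums of the positive libraries. In negative replicate 3, Reg1 (563 CPM) and Zg16 (484 CPM) made up most of the sum. The elastase Cela1 (3.06 ± 0.47) and the lipase-related Pnliprp2 (4.49 ± 0.61) passed. Rbpjl (2.36, edgeR adjusted p = 0.0364) lost its call without any 1 library but positive replicate 2, and was at 1.74 without positive replicate 3. Islet genes rose in 4 of 16 and fell in 1 (4 and 1 adjusted over the list alone), with a median of 0.84 (camera adjusted p = 0.0579, and 0.000744 without negative replicate 3, 0.0477 with DESeq2 size factors and 0.0295 with the replicate block, with 0.663 the highest over the alternatives). The peptide hormone Pyy was higher (5.19 ± 0.54), and Ppy was at 3.60, 2.45 and 4.18 CPM against 0, 0.22 and 0.07 CPM (log2 4.97, and 6.50 without negative replicate 2; call lost without both libraries numbered 3, adjusted p = 0.0538; range over the alternatives 1.08e-07 to 0.0538). Ins2, at 5.28, 0.95 and 5.09 CPM, had estimated counts of 1, 1 and 0 in the negative libraries. The member that fell, Mafb (-3.75 ± 0.45, and -4.35 without positive replicate 2), is also a macrophage transcription factor.

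Markers of leukocytes were lower in the positive cells, that is, higher in the negative ones. All 20 macrophage and myeloid genes fell (20 adjusted over the list alone), with a median of -3.29 (camera adjusted p = 8.42e-10, and adjusted p = 0.48 with an estimated correlation). The receptor Csf1r was at 91.8 ± 36.0 CPM against 1068 ± 314 CPM (SD, n = 3 each; log2 -3.54 ± 0.41, edgeR adjusted p = 0.00127). The adaptors Tyrobp (-3.69) and Fcer1g (-3.63) and the lipopolysaccharide receptor Cd14 (-3.27) moved with it. Of 14 neutrophil genes 13 fell and 1 rose (13 and 1 adjusted over the list alone), with a median of -5.97 (camera adjusted p = 4.75e-08, and adjusted p = 0.48 with an estimated correlation). The receptors Csf3r (-6.12 ± 0.41) and Cxcr2 (-5.67 ± 0.31) fell with Retnlg, G0s2 and S100a9, and the member that rose was lactoferrin (Ltf, 2.95 ± 0.38), which exocrine epithelia also secrete.

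Lymphocyte genes fell in 9 of 14 and rose in 0 (9 and 0 adjusted over the list alone), with a median of -2.79 (camera adjusted p = 0.000968, and adjusted p = 0.594 with an estimated correlation). The B cell gene Cd19 (-3.59, edgeR adjusted p = 0.0147) lost its call without positive replicate 3 (adjusted p = 0.0581; range over the alternatives 4.27e-06 to 0.109) and was at -4.96 without positive replicate 2. The T cell gene Cd8a (-4.72) was at -3.39 without negative replicate 3, and at -5.37 without positive replicate 2. Its call was lost with the replicate block (adjusted p = 0.0515), with limma-voom (0.0703) and without both libraries numbered 3 (0.061; range over the alternatives 1.57e-07 to 0.0703). The summed CPM of the list overlapped between groups, at 504.5, 4596 and 4241 in the positive and 5325, 1838.5 and 2122 in the negative libraries. Most of it was Jchain, the joining chain of secreted antibodies, which was at 492, 4485 and 4152 CPM in the positive and 5073, 1732 and 1771 CPM in the negative libraries, and did not pass (log2 0.09, edgeR adjusted p = 0.942). Its sign turned without positive replicate 2 (-0.30) or 3 (-0.20), or negative replicate 2 or 3 (-0.17 each). Antigen presentation genes fell in 14 of 15 and rose in 0 (14 and 0 adjusted over the list alone), with a median of -2.41 (camera adjusted p = 1.17e-06, and adjusted p = 0.48 with an estimated correlation). The class II regulator Ciita (-4.64 ± 0.29) and the class II genes H2-Aa (-4.38 ± 0.48) and H2-DMa (-3.79 ± 0.39) were among them.

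Endothelial genes fell in 10 of 14 and rose in 0 (10 and 0 adjusted over the list alone), with a median of -2.56 (camera adjusted p = 8e-05, and adjusted p = 0.48 with an estimated correlation). They summed to 30.4 to 57.8 CPM in the positive and 154 to 223 CPM in the negative libraries, and included von Willebrand factor (Vwf, -2.97 ± 0.37) and Eng (-3.36 ± 0.32). Fibroblast genes had a median of -2.13 (camera adjusted p = 0.00349, and adjusted p = 0.711 with an estimated correlation), with 3 of 20 falling and 0 rising (1 and 0 adjusted over the list alone). The collagen Col1a1 was at 7.4, 66 and 152 CPM against 83.1, 736 and 261 CPM and did not pass (log2 -2.26, edgeR adjusted p = 0.152), but did with the replicate block (-2.62, adjusted p = 0.0479; range over the alternatives 0.0479 to 0.435). Mmp2 fell (-2.23 ± 0.46), and Pdpn (-2.0, edgeR adjusted p = 0.0284) was at -1.29 without negative replicate 2 (adjusted p = 0.0671) and also lost its call without any 1 positive library (range over the alternatives 0.000924 to 0.0744). Erythroid genes fell in 2 of 5 and rose in 0 (2 and 0 adjusted over the list alone), with a median of -2.70 (camera adjusted p = 0.0627, and 0.0349 without negative replicate 2, 0.0358 without positive replicate 3, 0.0457 with the replicate block and 0.0462 with fry, with 0.541 the highest over the alternatives). The haemoglobin gene Hba-a2 was at -3.41, and at -2.46 without negative replicate 1.

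**Figure D3:**
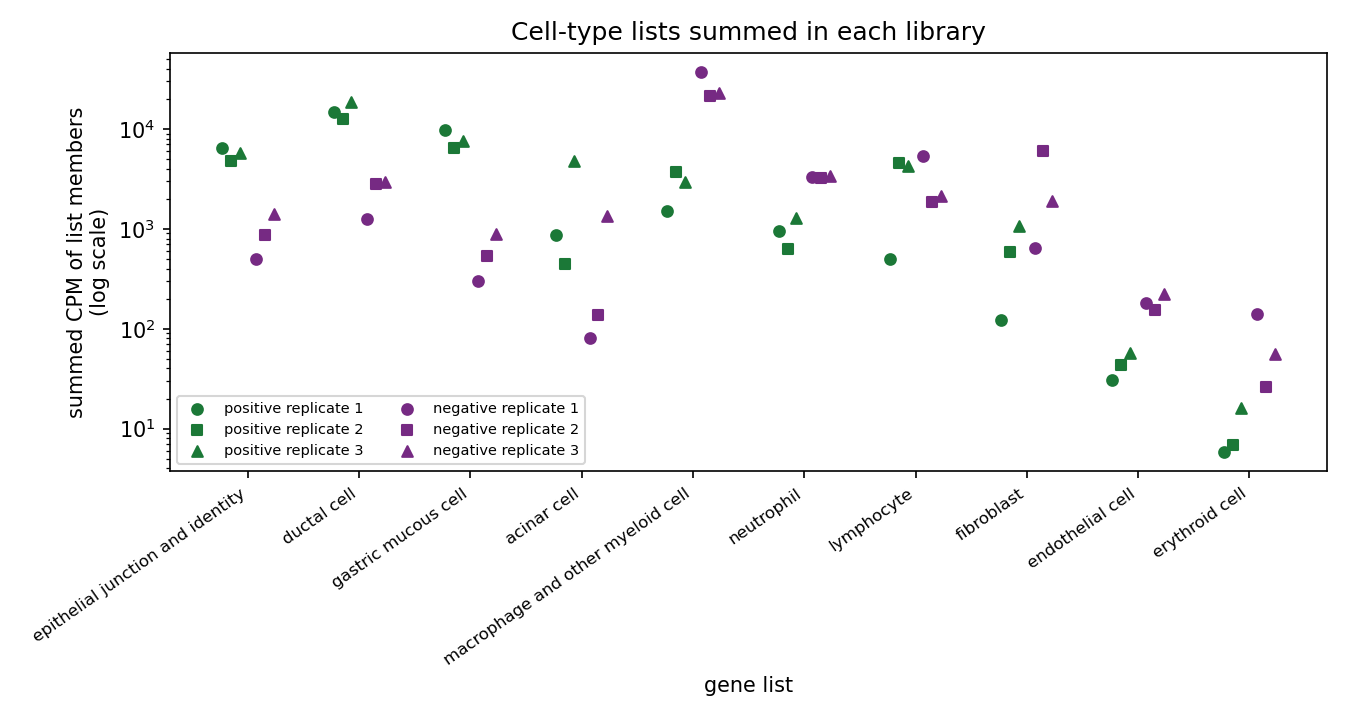
Summed CPM (log axis) of the tested members of 10 cell-type lists in each library, coloured by group (green positive, purple negative), with a symbol for each replicate number. The epithelial junction sums were 4805 to 6502 CPM in the positive and 495 to 1410 CPM in the negative libraries, while the acinar list was highest in positive replicate 3 (4833 CPM) and the fibroblast list in negative replicate 2 (5985 CPM). Most of the neutrophil sums of positive replicates 1 to 3 (960.6, 629.8 and 1290.5 CPM) was Ltf (918.5, 548.1 and 1235.8 CPM).

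Genes of the epithelial-mesenchymal transition fell in 10 of 15 and rose in 1 (11 and 1 adjusted over the list alone), with a median of -2.28 (camera adjusted p = 7.51e-05, and adjusted p = 0.48 with an estimated correlation). Tgfbi (-4.15 ± 0.35), Zeb2 (-3.81 ± 0.37), S100a4 (-3.65 ± 0.29) and Fn1 (-2.73 ± 0.28) were the 4 with the smallest adjusted p. These are also expressed by macrophages, whose markers were higher in the same libraries. Tuft cell genes moved both ways: 6 of 16 rose and 9 fell (7 and 9 adjusted over the list alone), with a median of -1.70 (camera adjusted p = 0.343). The taste channel Trpm5 (3.65), Sh2d6 (3.72, and 2.93 without positive replicate 3) and Avil (3.30, and 4.34 without negative replicate 3) rose. The transcription factor Pou2f3 (3.10) lost its call without positive replicate 3 (adjusted p = 0.0538) and with the replicate block (0.0595; range over the alternatives 0.000738 to 0.0722). Those that fell included Alox5ap (-3.76), Ltc4s (-3.31), Plcb2 (-3.68) and Siglecf (-4.47, and -5.07 without positive replicate 3), genes that leukocytes also express.

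Stem cell genes rose in 12 of 22 and fell in 3 (12 and 3 adjusted over the list alone), with a median of 1.36 (camera adjusted p = 0.00704, and adjusted p = 0.48 with an estimated correlation). Prom1, which encodes CD133 (gene 19126, chromosome 5, 43993621 to 44102047), was at 1527 ± 215 CPM against 102 ± 35.8 CPM (SD, n = 3 each; log2 3.91 ± 0.34, edgeR adjusted p = 0.000714). Alcam (1.61 ± 0.18) and the telomerase gene Tert (2.56 ± 0.40) rose, while the transporter Abcg2 (-2.69 ± 0.23) and Aldh1a2 (-2.53, and -3.16 without positive replicate 3) fell, as did Cxcr4 (-2.72), whose call was lost without both libraries numbered 3 (adjusted p = 0.0601; range over the alternatives 4.84e-08 to 0.0601). Genes of the epithelial junction list, with a median of 2.77, were higher in the same libraries. Cd44 was at -0.11 (edgeR adjusted p = 0.657), and at 0.03 without negative replicate 2. Of the mitosis genes 21 of 30 fell and 2 rose (24 and 2 adjusted over the list alone), with a median of -1.29 (camera adjusted p = 2.37e-06, and adjusted p = 0.48 with an estimated correlation). Birc5 (-1.39 ± 0.21), Aurkb (-2.15 ± 0.34) and Ccnb2 (-1.33 ± 0.21) fell, and the kinase Plk1 (1.2) and kinesin Kif23 (0.99) rose, the latter not without both libraries numbered 3 (adjusted p = 0.0972; range over the alternatives 0.00136 to 0.0972). The macrophage (median -3.29) and neutrophil (-5.97) lists were lower in the same libraries. DNA replication genes fell in 5 of 30 and rose in 2 (0 and 0 adjusted over the list alone), with a median of -0.41 (camera adjusted p = 0.035, and adjusted p = 0.711 with an estimated correlation). This call was also lost without positive replicate 1 (adjusted p = 0.0839), positive replicate 2 (0.149) or negative replicate 1 (0.0796), and Mcm3 (-1.10 ± 0.23) was among the members that fell.

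Cytokine, chemokine and receptor genes rose in 8 of 49 and fell in 22 (9 and 23 adjusted over the list alone), with a median of -0.65 (camera adjusted p = 0.014, lost without negative replicate 2 at 0.0551, and adjusted p = 0.48 with an estimated correlation). Interleukin 1 beta (Il1b) was at 32.2 ± 10.4 CPM against 2007 ± 539 CPM (SD, n = 3 each; log2 -5.96 ± 0.39, edgeR adjusted p = 0.000603), and Cxcl2 (-5.09 ± 0.40) and Csf1 (-3.10 ± 0.27) fell with it. Cxcl17, a mucosal chemokine, rose (4.79 ± 0.27), as did Il34 (2.63). Interferon response genes fell in 6 of 23 and rose in 1 (5 and 1 adjusted over the list alone), with a median of -0.81 (camera adjusted p = 0.014, lost without positive replicate 1 at 0.0839, and adjusted p = 0.711 with an estimated correlation). Stat1 (-1.53 ± 0.23) was among them. The macrophage (median -3.29) and neutrophil (-5.97) lists were lower in the libraries in which cytokine and interferon genes fell. Basement membrane and integrin genes rose in 12 of 32 and fell in 4 (13 and 4 adjusted over the list alone), with a median of 0.46 (camera adjusted p = 0.035, and adjusted p = 0.781 with an estimated correlation). That call was lost without positive replicate 2 (0.0503), positive replicate 3 (0.0619), negative replicate 1 (0.151) or negative replicate 3 (0.0595). The integrin Itgb6 (3.51, and 4.21 without negative replicate 2) and the laminin chain Lamb3 (2.58 ± 0.39) rose, and the fibronectin receptor chain Itga5 (-1.53 ± 0.23) fell.

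The Hedgehog, Wnt, Notch and nuclear receptor lists were not called by camera. In the Hedgehog list 5 of 13 rose and 0 fell (5 and 0 adjusted over the list alone), with a median of 0.49 (camera adjusted p = 0.29). The ligand Shh (gene 20423, chromosome 5, 28456840 to 28467101) was at 58.5 ± 18.3 CPM against 2.15 ± 1.28 CPM (SD, n = 3 each; log2 4.74 ± 0.51, edgeR adjusted p = 0.0011). The other ligands Dhh (3.33) and Ihh (3.56, and 4.39 without negative replicate 3) rose too, as did the signal transducer Smo (1.93), except without both libraries numbered 3 (adjusted p = 0.0958; range over the alternatives 5.24e-05 to 0.0958). Of the pathway's targets, Ptch1 rose (0.63, edgeR adjusted p = 0.045), a call that was lost without any 1 library but positive replicate 3 (highest adjusted p 0.151, range over the alternatives 0.0322 to 0.151). Gli1, at -2.58, did not pass (edgeR adjusted p = 0.0933) and passed with DESeq2 (0.0373; range over the alternatives 0.0373 to 0.285). In the Wnt list 5 of 21 rose and 3 fell (5 and 3 adjusted over the list alone), with a median of 0.39 (camera adjusted p = 0.131, and 0.0405 with fry, with 0.594 the highest over the alternatives). The co-receptor Lrp5 (1.5 ± 0.18) and the receptor Fzd3 (3.67, and 4.55 without negative replicate 2) rose, and Lef1 (-3.16) fell, a call lost without both libraries numbered 3 (adjusted p = 0.0827; range over the alternatives 1.49e-05 to 0.0827). In the Notch list 6 of 21 rose and 4 fell (7 and 7 adjusted over the list alone), with a median of 0.39 (camera adjusted p = 0.747). The ligand Jag1 rose (1.25 ± 0.18), while Notch2 (-1.47 ± 0.15), Lfng (-2.16 ± 0.23) and Mfng (-3.14 ± 0.52) fell. In the nuclear receptor list 10 of 39 rose and 7 fell (11 and 7 adjusted over the list alone), with a median of 0.01 (-0.02 with DESeq2 size factors; camera adjusted p = 0.747). The members that fell included Nr4a1 (-1.83 ± 0.17), Nr4a2 (-2.27 ± 0.29), Nr4a3 (-4.17, and -4.85 without positive replicate 2) and the vitamin D receptor Vdr (-2.09 ± 0.25).

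Metabolic and stress lists were not called by camera either. Hypoxia and glycolysis genes rose in 3 of 24 and fell in 5 (3 and 4 adjusted over the list alone), with a median of 0.01 (-0.02 with DESeq2 size factors), a mean of -0.03 and a camera adjusted p of 0.34 (downward), which was 0.0033 without positive replicate 3. Pfkp (-2.31 ± 0.38) and Pfkfb4 (-1.59 ± 0.18), which act on fructose 6-phosphate, fell. Cholesterol synthesis genes rose in 2 of 22 and fell in 2 (2 and 2 adjusted over the list alone), with a median of -0.01 (0.11 without normalization factors; camera adjusted p = 0.964). Tm7sf2 (1.56 ± 0.27) rose and Mvd (-1.42 ± 0.25) fell. Fatty acid genes rose in 6 of 22 and fell in 7 (9 and 8 adjusted over the list alone), with a median of 0.10, a mean of -0.01 and a camera adjusted p of 0.903 (downward). Malic enzyme (Me1, 3.32 ± 0.51) rose, and Dgat1 (-2.27 ± 0.22) and ATP citrate lyase (Acly, -1.29 ± 0.17) fell. Dissociation stress genes rose in 6 of 20 and fell in 8 (6 and 8 adjusted over the list alone), with a median of 0.04, a mean of -0.04 and a camera adjusted p of 0.601 (downward). Atf3 (1.47 ± 0.18) and Dnajb1 (1.51 ± 0.18) rose, while Ier3 (-1.76 ± 0.18) and Egr2 (-1.97 ± 0.22) fell. Of 13 mitochondrially encoded genes 0 rose and 0 fell (0 and 0 adjusted over the list alone), with a median of 0.30 (camera adjusted p = 0.327), and their sums ran from 14532 to 24237 CPM over the 6 libraries.

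In the authors' deposited table, 568 of 13787 genes were at a false discovery rate under 0.05, of which 228 were higher and 340 lower in the positive cells. All 568 were also past the threshold in the edgeR test, in the same direction. The reverse did not hold: the authors' table listed 5329 of the genes called by edgeR, and only the 568 were under 0.05 there. Kras (0.525) and Trp53 (0.31), for example, were not. Over the 13712 genes in both, the log2 ratios of the authors' deposited table and of the edgeR fit correlated at r = 0.985 across genes, which are not independent replicates, and 97.5% had the same sign. The authors' deposited table gave Msi2 a log2 ratio of 1.97 at a false discovery rate of 0.00902, and Epcam one of 3.13 at 0.392.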

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

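The run without both libraries numbered 3 was chosen after the data had been seen, and the other settings before. The counts of 2774 higher and 2641 lower genes stayed within 1.5 times under each alternative normalization, filter, test, block and single library left out. In that run, with fewer samples, the count of higher genes (1794) left this range and that of lower genes (1914) did not. Leaving out 1 library gave 1974 to 2513 higher and 2003 to 2382 lower genes, and the DESeq2 Wald test gave 3216 and 3238. Of the 5415 calls, the DESeq2 Wald test shared 5387 and limma-voom 5257, all in the same direction. With the number as a replicate block, 2444 genes were higher and 2339 lower. Deviations from the group means correlated across genes at 0.03, 0.13 and 0.16 between libraries with numbers 1, 2 and 3, so the numbers were not taken to pair the samples, although 5 of 6 libraries correlated best with their own number, a hint from the data and not from the design. Of 154 tested named genes, 141 were past the threshold and 112 remained so under every setting run for them, while 17 lost the call without some single library and 12 under another setting alone. Msi2 ranged from 1.92 to 2.08 over these settings. Scaling the libraries to the epithelial junction and identity list, a separate test, moved all genes down by a median of 2.9 (log2): 119 genes were then higher and 11872 lower, and Msi2 was at -0.96 (adjusted p = 0.152). Signs turned for Msi1, at 0.70 with limma-voom and from -1.17 to 0.15 without single libraries, and for COX1, at 0.18 without both libraries numbered 3 and from -0.261 to 0.075 without single libraries. Neither passed the threshold in any of these.

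With an estimated correlation camera called 0 lists. The adjusted p was then 0.48 for the ductal, gastric mucous, basal and squamous, epithelial junction, epithelial-mesenchymal transition, macrophage, neutrophil, endothelial, mitosis, stem cell, pancreas development, cytokine and antigen presentation lists, 0.594 for lymphocytes, 0.711 for the acinar, fibroblast, DNA replication and interferon lists and 0.781 for basement membrane and integrin. With fry, 15 lists were called, and the acinar (0.136), fibroblast (0.172), lymphocyte (0.07), DNA replication (0.169), interferon (0.172) and basement membrane (0.175) lists were not, while the erythroid (0.0462) and Wnt (0.0405) lists were called. Without single libraries the adjusted p ran from 0.00241 to 0.149 for DNA replication, 0.0006 to 0.0839 for interferon response, 0.000327 to 0.151 for basement membrane and integrin, and 0.00864 to 0.0551 for cytokines. Lists near 0 turned direction without being called. These were cholesterol synthesis (0.918 with fry, 0.999 with no filter, 0.283 to 0.846 without single libraries), nuclear receptors (0.827 with fry, 0.188 to 0.962) and fatty acid synthesis (0.975 with the replicate block, 0.704 to 0.981). Apart from the smaller runs, the cause was not tested. Depth limits genes near 3 counts, such as Ptf1a. In the simulation, changes of 2-fold were seldom recovered with 3 libraries a group. There 100 genes changed 2-fold and 100 changed 4-fold, whereas 38.2% of tested genes were called in the data. Adjustment is stricter where fewer genes change, so the recovery in these data may differ and was not measured.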

Other observations

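The tests of normalization, of Trp53 and of library depth, the gene families and the check of what the epithelial scale could show were chosen only after the results were seen. Gene families defined by the letters that open a symbol were tested as well. Some of their members, such as Krt18, Cldn4, Sox9, Ccl2 and Clec4d, were also in the fixed lists, so these families are not independent of those lists. Of 159 families with at least 10 tested members, 4 were over-represented among higher genes and 5 among lower genes (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over 318 tests, with genes that are not independent). The same test found Zfp under-represented among lower genes (17 of 324, against 18.61% of tested genes; adjusted p = 5.33e-10 by the exact test). Eif was under-represented among higher genes (2 of 53, against 19.55%; adjusted p = 0.0478 by the exact test). Claudins, the strand proteins of tight junctions, were higher in 9 of 14 and lower in 0 (adjusted p = 0.0168 by the exact test), with Cldn2, which forms cation pores, at log2 3.30, and Cldn4 at 3.51. Cldn4 was at 4.39 without negative replicate 2 and lost its call without both libraries numbered 3 (adjusted p = 0.0564; range over the alternatives 1.63e-09 to 0.0564). Keratins were higher in 11 of 19 and lower in 1 (adjusted p = 0.0158 by the exact test), with Krt18 at 2726 ± 659 CPM against 208 ± 95.0 CPM (SD, n = 3 each). Krt20 was at log2 3.29, Krt23 at 3.79, and Krt80 was the member that fell (-0.98), a call lost without positive replicate 1 or 2 or negative replicate 1 or 3 (adjusted p from 0.0638 to 0.0774; range over the alternatives 0.00379 to 0.0774). Sox transcription factors were higher in 7 of 10 and lower in 0 (adjusted p = 0.0338 by the exact test), among them Sox21 (4.09), Sox4 (2.76) and Sox9 (2.98). The fourth family, Samd, was higher in 7 of 11.

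C-type lectins were lower in the positive cells in 15 of 24 and higher in 0 (adjusted p = 0.00027 by the exact test), among them Clec5a (-4.60) and Clec4e (-4.97), receptors of myeloid cells. Toll-like receptors were lower in 10 of 12, with Tlr2 at -3.64 and Tlr13 at -3.77 (-4.45 without positive replicate 2), while Tlr3, the receptor for double-stranded RNA, was higher (1.47). CC chemokines were lower in 10 of 14 (adjusted p = 0.00187 by the exact test), with Ccl6 at 542 CPM against 5170 CPM (log2 -3.25, and -3.94 without positive replicate 2) and Ccl9 at 136 CPM against 1418 CPM. The families Gpr (16 of 39) and Snx (13 of 29) were the other groups among lower genes. The mast cell proteases Mcpt1 (log2 4.25) and Mcpt2 (4.86, and 5.79 without negative replicate 3) were higher in the positive libraries, unlike most leukocyte genes.

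Leukocyte genes were lower and epithelial genes higher in the positive libraries. The medians of the epithelial junction and neutrophil lists lay at least 8.72 apart (log2), a gap that a single factor per library cannot produce, since it moves both medians alike and leaves their difference as it is. Leukocytes in the negative libraries remain a candidate source: of a second list of 25 pan-leukocyte genes, none of them in the first lists, 25 of 25 (100%) were lower in the positive libraries, with a median of -3.56, although a sort for EpCAM would remove leukocytes. After 20 of 20 macrophage genes had been seen to fall, pan-leukocyte genes were likely to fall too, so this list adds little. Among the most abundant negative genes were Fn1, Chil3 and Lyz2, and how many of the 25 genes these tumour cells express themselves is not known here. Markers of several lineages were lower together: 20 of 20 macrophage, 13 of 14 neutrophil, 9 of 14 lymphocyte and 10 of 14 endothelial genes. For these genes this argues against a change within recombined tumour cells alone, which would have to express markers of all these lineages. Trp53, lower in the positive cells (log2 -1.61), does not decide it. Bulk libraries cannot separate an unrecombined cell from a tumour cell state that transcribes more Trp53. For the epithelial genes such a change stays open.

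Genes of the intestinal epithelium were higher in negative replicate 3 than in the other negative libraries, such as Apoa4 at 810 CPM against 10.4 and 5.0 CPM, and Alpi at 480 CPM against 9.9 and 1.8 CPM. Depth alone was excluded, since a second list of intestinal genes lay at a median of 23.8 times the higher of the other 2 negative libraries. Intestinal epithelium in that library may be the source: 21 of 24 genes of that list (87.5%) reached 5 times the other negative libraries, and such cells would pass an EpCAM sort. The list is not specific to that library, since in the positive libraries Prap1 was at 367, 694 and 797 CPM, Fcgbp at 167, 111 and 148 CPM, and Clca1 at 46.7, 215 and 27.9 CPM against 115 CPM in negative replicate 3. The design sets this library apart by nothing but its number, so a difference in the biology of its tumour was not tested.

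The higher genes could reflect the same epithelial cells diluted by other cells in the negative libraries, and the test run could not decide this. With libraries scaled to the epithelial junction and identity list, 119 genes were higher, 4.29% of the number under TMM, which met the bound of at most 5% set beforehand for dilution, and 11872 were lower. That scale moved all genes down by a median of 2.9 (log2), which 23.5% of the genes higher under TMM exceeded, so the share over 25% set beforehand against dilution was out of reach, and once this was seen the 4.29% was no longer counted for dilution, while the direction of a gene or list on this scale carries no weight by itself. Without negative replicate 3, whose intestinal genes may raise the scale, 155 were higher (6.17%) and 12298 lower. There 29.05% exceeded the shift (3.21) in fold change, whether or not they would pass the threshold on this scale. A share over 25% was therefore at best barely within reach. The share seen lay between the bounds, so dilution and a change within the epithelial cells cannot be told apart. Among the lists, 7 of 15 gastric mucous genes (5 of 15 without negative replicate 3), 7 of 26 acinar genes (18 of 27) and 4 of 18 ductal genes (2 of 18) were higher on this scale. Lower were 1 gastric mucous gene (1 without negative replicate 3), 2 acinar genes (3) and 2 ductal genes (2). Of all genes, 89 were higher in both runs, among them Gkn2 (2.59), Sftpd (2.80), Vsig2 (2.62) and Shh (2.05).

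The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05 (edgeR test). The real split gave 5415 genes past the threshold, as many as in 1 split, and the highest other split gave 0. Each other split put positive and negative libraries together on both sides, so the difference between the groups became part of the spread. The contrast of 5415 with 0 therefore cannot speak against chance.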
